A study of Arabidopsis thaliana with 6 samples.

How the data were processed

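Messenger RNA was measured in 0.5 cm tips of primary roots from Arabidopsis thaliana seedlings 5 days after planting. The 2 genotypes were wild type Columbia (Col) and ore15-2, a T-DNA insertion line of ORE15 in the same background, with 3 libraries each. Per the labels' protocols, poly(A) RNA was purified from total RNA with an integrity number of 6.7 or higher, made into libraries with a stranded TruSeq mRNA kit and sequenced on an Illumina HiSeq instrument. The labels give 2 seedlings per genotype although 3 libraries per genotype are listed, and nothing says that the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

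The authors deposited a table of read counts per gene and a table of RPKM values. Per the submitters' processing notes, the tools were FastQC, cutadapt, TopHat2 and HTSeq with the TAIR10 genome. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and an overlapping antisense gene may not be separated. The counts cover 18734 genes and the RPKM values cover 18340. In all 18340 shared genes the deposited RPKM values and counts implied a single gene length in the 6 libraries within a relative tolerance of 0.0001, so the RPKM values restate the counts and are no separate measurement.

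Gene symbols, positions and biotypes came from the TAIR10.1 reference annotation, in which 18690 of the listed IDs had an entry. The 44 others were 20 mitochondrial genes, 12 chloroplast genes and 12 rows with ENSRNA identifiers. Total counts ranged from 6396903 to 20333352 per library. In the deepest and shallowest library a floor of 3 counts corresponds to 0.136 and 0.596 CPM (counts scaled to a common library size). Intervals and floors cover counting error only.

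Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, with TMM scaling, the filterByExpr filter and genotype as the only term. Adjusted p is the Benjamini-Hochberg value over the 18726 genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its absolute value divided by the square root of F. Changes per library are log2 CPM, with a prior count of 2, less the mean of the Col libraries. CPM values, floors included, use the TMM-scaled library sizes.

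A total of 31 gene lists with 473 members was fixed before the data were examined, and 401 members were kept. Of the rest, 64 were not in the count table and 8 had a name that the reference does not give for the ID. ORE15 was kept although the reference does not name it either, because it is the gene under study. Lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. fry tests whether a list's genes move one way on balance and does not compare them with other genes. RPKM values were tested with limma on log2(RPKM + 1) for genes with a mean RPKM of at least 1, so fold changes of low genes are understated on that scale.

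The named genes follow a rule set before the data were examined. ORE15 comes first. Then come the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the CPM values of the genotypes. In lists on auxin, cytokinin, the meristem, the cell cycle and growth regulators, up to 4 members past the threshold are named, or the 2 with the smallest p where none passed. In the remaining lists up to 2 members past the threshold are named. Genes outside the rule are named where a count is 5 or fewer, and these were chosen after their values were seen.

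The fraction of changed genes within 100 tested genes on either side of ORE15 was compared with that of all other tested genes by a two-sided Fisher exact test. A scan for runs of raised genes along each chromosome was added after that count was seen. It used genes with a mean log2 CPM above 3, clipped fold changes at 2 on the log2 scale and was compared with 100 shuffles of gene order.

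Alternatives covered RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a replicate block, organelle genes left out, each library left out in turn, other windows, another pseudocount and a fold minimum of 1.5. Leaving out ore15-2 replicates 1 and 2 together, and leaving out the genes of the raised chromosome 1 block, were chosen after seeing the data.

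The code was tested on simulated data with the means and library sizes of these samples. For ore15-2 against Col, edgeR on 18725 simulated genes recovered 90 of 100 genes changed 2-fold and 100 of 100 genes changed 4-fold, with 12 false calls. The simulation changed only genes with a mean of at least 5 CPM and gave each gene the same dispersion in every library. It held no libraries that stand apart, unlike ore15-2 replicates 1 and 2. It therefore checks the code and gives no error rate for the real data. Summaries and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.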

Results

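The data are RNA-seq counts from primary root tips of wild-type Arabidopsis (Col) and of ore15-2, which carries a T-DNA insertion in ORE15, a gene for a PLATZ family transcription factor. Each genotype had 3 libraries. Total counts were 17433440, 20333352 and 19285639 in Col replicates 1 to 3, and 6706712, 6396903 and 16503138 in ore15-2 replicates 1 to 3. Mitochondrial genes took 0.183%, 0.215% and 0.250% of the counts in Col, 2.91% and 3.20% in ore15-2 replicates 1 and 2, and 0.328% in ore15-2 replicate 3. On the principal component with the most variance (68.8%), the Col libraries lay between -36.7 and -27.8, ore15-2 replicate 3 at -4.07, and ore15-2 replicates 1 and 2 at 33.5 and 67.3. No pair of libraries agreed within sampling noise, the lowest chi-square per gene being 2.14, between Col replicates 2 and 3.

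**Figure D1:**
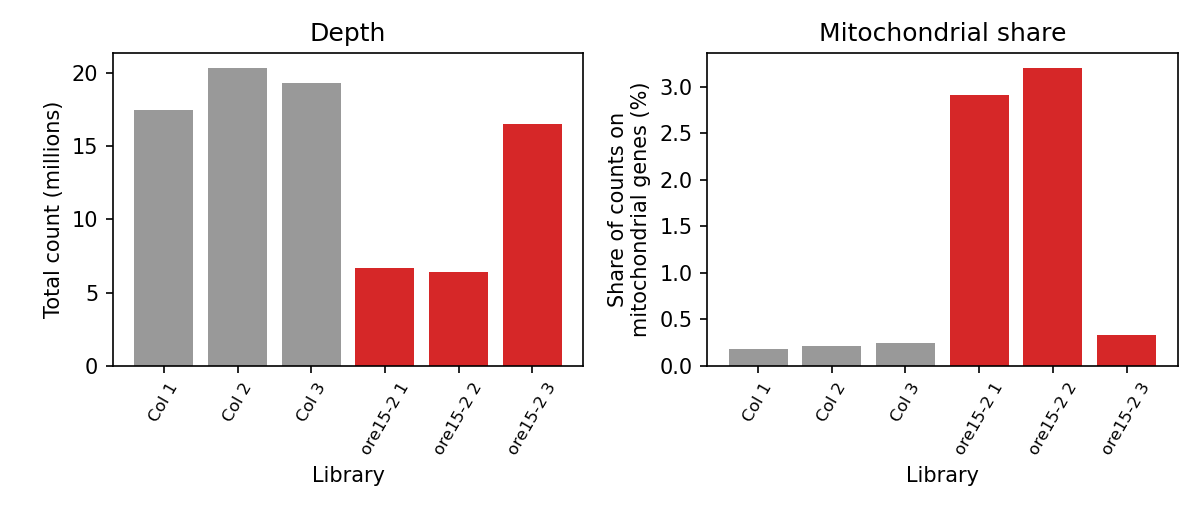
Bars give the total count (left) and the share of counts on mitochondrial genes in percent (right) for each of the 6 libraries, Col in grey and ore15-2 in red. The mitochondrial share was 2.91% and 3.20% in ore15-2 replicates 1 and 2 and at most 0.328% in the other libraries.

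ORE15 (AT1G31040; TAIR10.1 chromosome 1, 11069510 to 11072564, minus strand) is taken to be the gene that the insertion line targets. The reference gives no symbol for this ID, and neither the labels nor the files pair it with ORE15, so the pairing rests on background knowledge. Its counts were 13, 12 and 8 in Col replicates 1 to 3, and 0, 0 and 1 in ore15-2 replicates 1 to 3. The mean was 0.534 ± 0.146 CPM (SD, n = 3) in Col, and the pooled level in ore15-2 was 6.57% of that in Col, with an exact 95% counting interval of 0.162% to 39.2%. The filter on low counts removed the gene from the test. Without that filter edgeR gave a log2 fold change of -3.65 with adjusted p = 0.0166, and DESeq2 gave -3.66 with adjusted p = 0.0371. The gene passed the filter in the edgeR fits that left out ore15-2 replicate 1, 2 or 3. There the changes were -3.38, -3.45 and -5.99, with edgeR adjusted p = 0.0652, 0.0253 and 0.0145. In the last of these fits ore15-2 had 0 counts of the gene.

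Comparing ore15-2 with Col asks which transcripts differ between root tips of this insertion line and of wild type. Every ore15-2 library also carries a raised block on chromosome 1, described below. Replicates 1 and 2 of ore15-2 had fewer counts and a higher mitochondrial share than every Col library. The changes therefore cannot be assigned to loss of ORE15 alone. Of 18726 genes tested, 1211 rose and 643 fell, and 713 of these changed at least 2-fold. Genes for iron uptake were among the largest falls. CYP82C4, an enzyme induced by iron deficiency, fell from 48.6 ± 2.97 to 4.78 ± 0.573 CPM (SD, n = 3; log2 fold change -3.30, SE 0.13, edgeR adjusted p = 6.73e-06), FRO2, the root ferric reductase, fell from 107.1 ± 4.25 to 17.8 ± 4.31 CPM, and NAS1, a nicotianamine synthase, fell from 139.3 ± 6.21 to 34.6 ± 7.31 CPM. The other large falls were NUDT8 (log2 fold change -2.46), GSTL1 (-2.25), DIN10 (-2.21), BT1 (-2.13) and MEE14 (-2.10). DIN10 is known as a gene induced in darkness, and it overlaps the neighbouring AT5G20260 by 82 bp.

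The largest rises included 5 mitochondrial genes, ORF240A, ATP6-2, RRN5, RRN18 and RRN26, with log2 fold changes of 4.98, 4.90, 4.48, 3.87 and 3.55. These followed the libraries with a high mitochondrial share. RRN26, the large mitochondrial ribosomal RNA, changed by 3.88 and 4.26 on the log2 scale in ore15-2 replicates 1 and 2 and by 0.71 in replicate 3. CAB2, a chlorophyll-binding protein of photosystem II also called LHCB1.1, lies in the raised block on chromosome 1 and rose by 3.11, with 3.13, 3.99 and 1.21 in the 3 libraries. RBCS3B, a Rubisco small subunit, rose by 2.86 (SE 0.48), with 18.1, 21.5 and 5.49 CPM in ore15-2 replicates 1, 2 and 3 and a mean of 1.91 CPM in Col. Both have near-identical copies between which reads may be split. XTH26, a cell wall enzyme of root hairs, rose by 2.44 (SE 0.38, edgeR adjusted p = 0.0045).

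The count of 1854 changed genes depended on single libraries. It was 746, 634 and 821 without Col replicates 1, 2 and 3, and 914, 2108 and 6612 without ore15-2 replicates 1, 2 and 3. With ore15-2 replicates 1 and 2 both left out, which treats the lone library as varying like Col, it was 3109, of which 1642 were among the 1854. Of the 54 named genes past the threshold, 27, 25 and 28 stayed past it without Col replicates 1, 2 and 3, and 30, 51 and 54 without ore15-2 replicates 1, 2 and 3.

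Genes beside ORE15 were changed more often than genes elsewhere. Within 100 tested genes on either side, 87 of 200 changed (43.5%), against 9.54% of all other tested genes (odds ratio 7.30, 95% interval 5.43 to 9.79, Fisher exact p = 1.6e-35, two-sided). On the side of lower coordinates 76 genes rose and 0 fell by edgeR. On the other side 5 rose and 6 fell. The odds ratio was 2.22 without ore15-2 replicate 3 and 12.1 without Col replicate 2. Genes in a window share a neighbourhood, so the test describes that window.

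The raised genes formed a block of 2.37 Mb on chromosome 1 from 8692630 to 11059037 (TAIR10.1), bounded by AT1G24530 and AT1G31020, and its last gene ended 10473 bp from ORE15. Of 401 tested genes in it, 318 rose and 1 fell, which is 26.3% of all raised genes. Over the 314 well-expressed genes the median log2 fold change was 0.95. The median fold was 1.93, 1.84 and 1.92 in ore15-2 replicates 1, 2 and 3, and 0.995, 1.01 and 1.00 in Col replicates 1, 2 and 3. The scan statistic was 15.9, against a highest value of 3.82 in 100 shuffles of gene order. A run of 31 genes on chromosome 5 also passed its shuffles, narrowly (1.99 against 1.91, median log2 fold change 0.22), and chromosomes 2, 3 and 4 did not. Outside the block 893 genes rose and 642 fell in the same fit. With the block genes left out and the fit repeated, 798 genes rose and 547 fell.

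**Figure D2:**
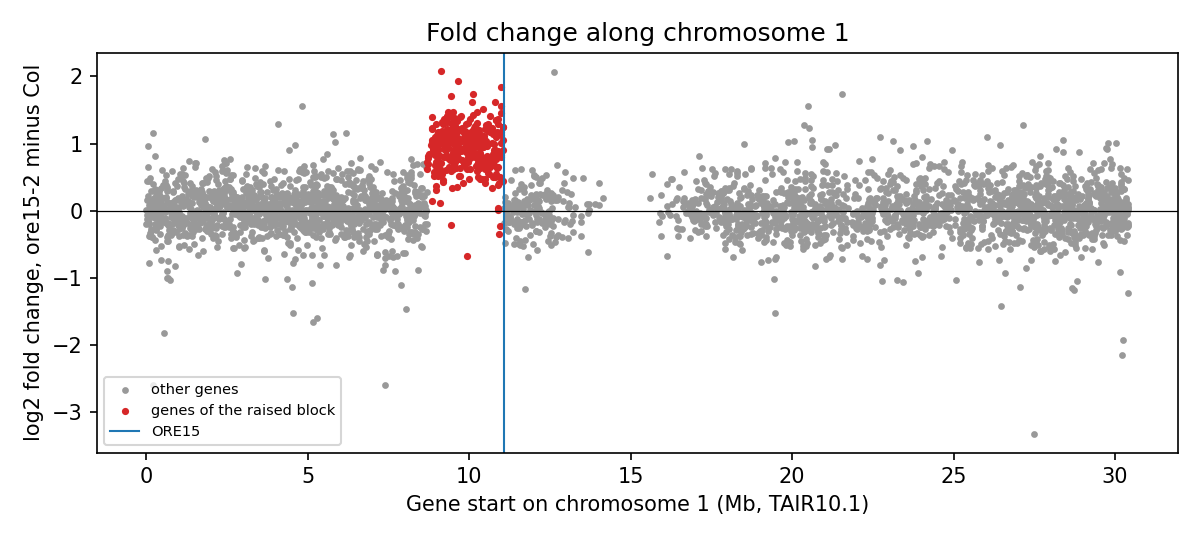
Each point is a well-expressed gene of chromosome 1, with its start in Mb (TAIR10.1) on the horizontal axis and its log2 fold change, ore15-2 minus Col, on the vertical axis. Red points are the 314 genes of the raised block, with a median of 0.95, and the blue line marks ORE15.

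Genes of root hair cells rose together. Of 22 measured members 16 rose and 0 fell by edgeR, and 19 rose when adjusted over the list alone. XTH13 and XTH12, wall-modifying enzymes of root hairs, rose by 1.54 and 1.48 on the log2 scale (SE 0.19 and 0.20). RSL4, a regulator of root hair growth that lies in the raised block, rose by 1.08. The list median was 1.15, with 0.81, 1.54 and 0.84 in ore15-2 replicates 1, 2 and 3. The list was called by camera (adjusted p = 1.59e-14), with adjusted p = 0.517 with an estimated correlation and 0.0665 with fry.

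The cell wall loosening list was called higher by camera over the 6 libraries. Of 15 members 5 rose, 1 fell and 9 did not pass, with 7 rising and 2 falling adjusted over the list alone. EXPA10, an expansin in the raised block, rose by 1.96, and XTH18 rose by 0.59, while the expansin EXPA4 fell by 0.54. The list median was 0.38, with 0.44, 0.62 and 0.31 in ore15-2 replicates 1, 2 and 3 (camera adjusted p = 0.00893, adjusted p = 0.832 with an estimated correlation, 0.0665 with fry and 0.0699 with ore15-2 replicates 1 and 2 left out). Of 6 phosphate starvation genes 4 rose, or 5 adjusted over the list alone. PAP17, an acid phosphatase that overlaps a neighbouring gene by 122 bp, rose by 1.24 and the phosphate transporter PHT1;4 by 0.68, and SQD2 and MGD2, enzymes of membrane lipid synthesis, rose by 0.39 and 0.71. The phosphate list was called by camera (adjusted p = 0.000689, median 0.53), with adjusted p = 0.227 with an estimated correlation. That estimate was -0.03, below the preset 0.01.

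Iron deficiency genes moved in both directions. Of 17 members 6 fell and 2 rose, or 7 and 3 adjusted over the list alone. IRT1, the root iron transporter, fell by 1.97 and MYB10, which overlaps a neighbouring gene by 340 bp, fell by 1.23, beside CYP82C4, FRO2 and NAS1, while the transporter OPT3 rose by 1.05 and NAS4 by 0.92. The list was called lower by camera (adjusted p = 3.76e-07) and by fry (adjusted p = 0.00672), with adjusted p = 0.116 with an estimated correlation. That estimate was -0.008, below the preset 0.01, so correlation between these genes does not account for the higher p. The list medians were -0.09, -0.10 and -0.39 in ore15-2 replicates 1, 2 and 3. The list test leaves out 3 measured genes whose names the reference does not give. Of these, chosen after their values were seen, S8H fell by 4.08 and FIT by 0.42, and IMA1 rose by 1.01.

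The phloem and xylem lists were called lower by camera over the 6 libraries. Of 10 phloem genes 3 fell and 0 rose by edgeR, the same counts as adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 3 called by DESeq2. SUC2, the sucrose transporter of companion cells, fell by 1.47, PP2-A1, a phloem lectin that overlaps a neighbouring gene by 284 bp, fell by 1.49, and SEOR1, a sieve element protein, fell by 0.68. The phloem medians were -0.27, -0.57 and -0.36 in ore15-2 replicates 1, 2 and 3 (camera adjusted p = 0.00142, and adjusted p = 0.593 with an estimated correlation and 0.0518 with fry). Of 13 xylem genes 1 fell, also adjusted over the list alone. This was ACL5, a thermospermine synthase that overlaps a neighbouring gene by 196 bp, which fell by 1.06. The xylem medians were -0.48, -0.17 and -0.07 (camera adjusted p = 0.0199, and adjusted p = 0.832 with an estimated correlation). The xylem call was lost without Col replicate 3 (adjusted p = 0.0742), without ore15-2 replicate 1 (adjusted p = 0.0902), with ore15-2 replicates 1 and 2 left out (adjusted p = 0.218) and with fry (adjusted p = 0.122).

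**Figure D3:**
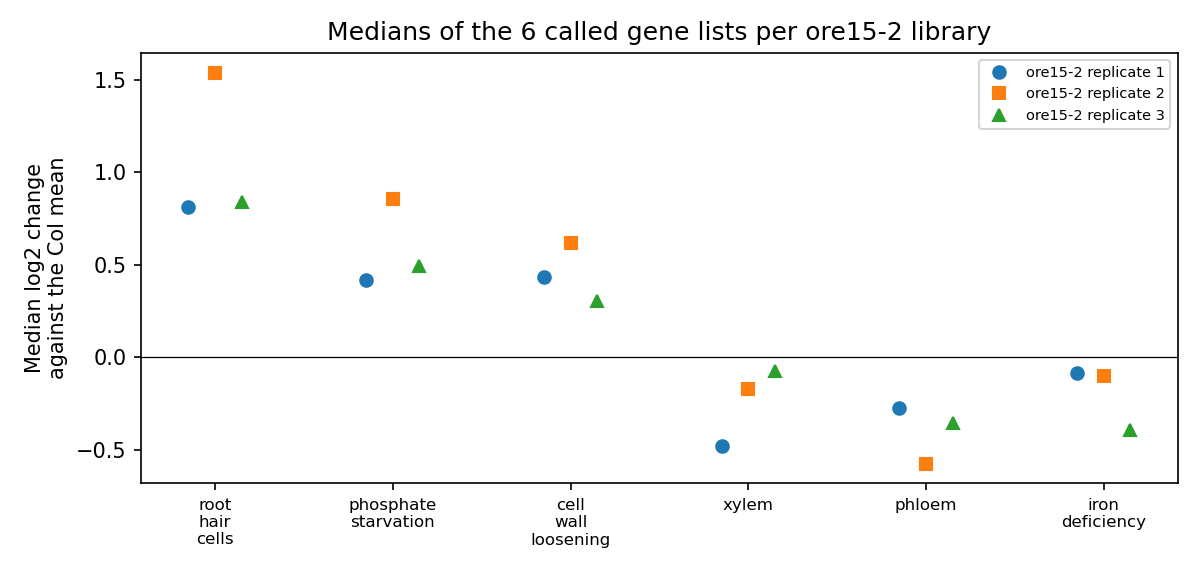
Points give the median log2 change against the Col mean of the 6 gene lists called by camera, for ore15-2 replicates 1 (circles), 2 (squares) and 3 (triangles). Root hair medians were 0.81, 1.54 and 0.84, and phloem medians were -0.27, -0.57 and -0.36.

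None of the auxin lists was called by camera. Among GH3 enzymes, which conjugate auxin to amino acids, GH3.17 rose by 1.07 and lies in the raised block, while YDK1 fell by 0.77 and WES1 by 0.38, the same 3 members as adjusted over the list alone. Of 21 Aux/IAA genes, repressors of auxin signalling, 0 passed by edgeR over all genes, 8 had an unadjusted p under 0.05, 5 were called by DESeq2 and 0 by limma-voom. Adjusted over the list alone, 2 rose and 3 fell. IAA13, which overlaps AT2G33300 by 1176 bp, and IAA8 had log2 fold changes of -0.46 and -0.35. Of 14 auxin transport genes 0 passed by edgeR, also adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, and ABCB4, which overlaps 2 neighbouring genes by 31 and 152 bp, and PIN7 had values of 0.38 and -0.32. The biosynthesis gene YUC6 fell by 0.56 (edgeR adjusted p = 0.0495), and the response factor ARF6, in the raised block, rose by 0.74 (edgeR adjusted p = 0.00246). Each was the only member of its list past the edgeR threshold, also adjusted over the list alone. The YUC6 call was lost under limma-voom, with a replicate block and without any single library other than ore15-2 replicate 3. ARF6 stayed past the threshold in these settings.

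Cytokinin lists were not called by camera over the 6 libraries. The receptors AHK3 and AHK2 went in opposite directions, AHK3, in the raised block, rising by 0.91 and AHK2 falling by 0.59 (edgeR adjusted p = 0.0355). AHK2 changed by -0.71, -0.90 and -0.32 in ore15-2 replicates 1, 2 and 3. Its call was lost without Col replicate 1, 2 or 3 and without ore15-2 replicate 1. The response regulator ARR3 rose by 0.74, with 0.35, 0.81 and 0.96 in ore15-2 replicates 1, 2 and 3. The medians of its list, the type-A ARRs, were -0.05, -0.46 and 0.26 in the same libraries. The list's direction was up with ore15-2 replicates 1 and 2 left out and down without ore15-2 replicate 3. Of 16 cytokinin metabolism genes, CYP735A2, which makes trans-zeatin, fell by 1.02, the activating enzyme LOG1 fell by 1.18, and the degrading enzyme CKX5, which overlaps UBC16 by 665 bp and 2 noncoding genes by 243 and 217 bp, rose by 0.64. Adjusted over the list alone, 1 rose and 3 fell. The calls of ARR3, CYP735A2, LOG1 and CKX5 were lost without Col replicate 1, 2 or 3. Those of LOG1 and CKX5 were also lost without ore15-2 replicate 1.

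Meristem and cell cycle lists and the PLATZ list were not called by camera over the 6 libraries. Of 19 root stem cell and meristem regulators 0 passed by edgeR, also adjusted over the list alone, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom, and SCZ and TMO7 had values of 0.64 and 0.49. Of 23 DNA replication genes ORC6, in the raised block, rose by 0.91, also adjusted over the list alone. Of 24 mitotic genes 0 passed by edgeR or DESeq2, 1 had an unadjusted p under 0.05, and CYCB2;4 and AUR1, which overlaps PFK6 by 290 bp, had values of -0.47 and -0.24. Of 9 endoreplication genes 0 passed by edgeR or DESeq2 and 0 had an unadjusted p under 0.05, with KRP6 at -0.35 and KRP2 at 0.20. The list leaves out the measured gene KRP4, whose name the reference does not give. KRP4, which overlaps a neighbouring gene by 926 bp, was at -0.27 with an unadjusted p under 0.05 (edgeR adjusted p = 0.139). The growth regulator GRF4 rose by 0.53, with 2 of 9 members of its list past the threshold adjusted over the list alone. Of the 5 other PLATZ genes kept in the list AT2G01818 fell by 0.63, and 3 fell adjusted over the list alone. The calls of GRF4 and AT2G01818 were lost without Col replicate 1, 2 or 3 and without ore15-2 replicate 1. The PLATZ medians were -0.52, -0.76 and -0.11 in ore15-2 replicates 1, 2 and 3. The list was called lower without ore15-2 replicate 3 (camera adjusted p = 0.0218), the library in which it fell least. The list test leaves out 3 measured PLATZ genes whose names the reference does not give. Of these, chosen after their values were seen, PLATZ1 fell by 0.88, PLATZ2 fell by 1.18 and RITF1 rose by 0.78.

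Photosynthetic genes split. Of 24 members 3 rose, RBCS2B, RBCS3B and LHCB1.1, the last of them in the raised block, and 6 fell, among them PSAD1 of photosystem I, which fell by 0.94, or 5 rose and 9 fell adjusted over the list alone. The median was -0.27 and the mean 0.26 (camera adjusted p = 0.265). The medians were -0.03, -0.08 and -0.61 in ore15-2 replicates 1, 2 and 3. Of 13 endodermis and suberin genes 3 rose, also adjusted over the list alone, among them GPAT5 and CASP4, which rose by 0.86 and 0.57 (camera adjusted p = 0.0745). In other lists not called by camera, SEN1, a gene induced in darkness, fell by 1.57, JAZ1 and VSP1 of the jasmonate list rose by 0.62 and 0.96, KIN1 and KIN2 of the abscisic acid list rose by 0.53 and 0.68, and ACS11 of ethylene synthesis rose from 1.46 ± 0.222 to 3.87 ± 1.49 CPM (SD, n = 3). The touch gene TCH3, which overlaps 2 neighbouring genes by 827 and 342 bp, rose by 0.95 and ZAT10, in the raised block, by 1.94, with 2.57, 2.02 and 0.82 in ore15-2 replicates 1, 2 and 3. The gibberellin receptors GID1A and GID1B went apart, at -0.61 and 0.48. The brassinosteroid gene ROT3, which overlaps a neighbouring gene by 83 bp, fell by 0.59, and the root cap gene FEZ, in the raised block, rose by 1.13. ROT3 and FEZ lay near the threshold (edgeR adjusted p = 0.0488 and 0.0472). Both calls were lost under limma-voom and without Col replicate 1, 2 or 3. Of 30 lists tested 24 were not called, and the nitrate list had 3 measured members and no set test.

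On the deposited RPKM values limma called 469 genes higher and 641 lower, of 17935 tested, and 958 of these 1110 were also called on the counts. On the counts more genes rose (1211) than fell (643). RPKM values carry no TMM scaling, and the TMM factors were 1.08 to 1.11 in Col but 0.92 and 0.79 in ore15-2 replicates 1 and 2. Without that scaling genes read lower in these 2 libraries than with it. The excess of falls therefore cannot be taken as an effect of genotype. The number of genes called on the RPKM values was 315, 250 and 342 without Col replicates 1, 2 and 3. It was 361, 1617 and 8435 without ore15-2 replicates 1, 2 and 3, the last with 1599 higher and 6836 lower. With ore15-2 replicates 1 and 2 both left out it was 3034.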

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

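Leaving out ore15-2 replicates 1 and 2 together, and leaving out the block genes, were chosen after the results were seen. The 1854 changed genes numbered between 1770 and 2520 under other scalings, filters and tools, 1529 with a fold of at least 1.5 and 1345 without the block genes. They ranged from 634 to 6612 when single libraries were left out and were 3109 with ore15-2 replicates 1 and 2 left out; the cause was not tested. Of the 54 named genes past the threshold, 54 stayed past it under RLE scaling and under DESeq2, 52 under upper-quartile scaling, where GRF4 and FEZ were lost, 46 under limma-voom and 44 with ore15-2 replicates 1 and 2 left out, and 0 of the 54 changed sign under any setting. The RPKM count ranged from 250 to 8435 and was 3034 in the same settings. The ORE15 level, as a pooled log2 ratio, ranged from -4.15 to -1.02. The last value is a bound that depends on the floor: without ore15-2 replicate 3, 0 counts remain, and it takes 3 counts over the group. With 3 counts per library the bound is -0.01, which shows no fall. The odds ratio beside ORE15 ranged from 2.22 to 12.1. Of 30 lists, 0 were called with an estimated correlation, where 2 had an unadjusted p under 0.05, and 2 with fry, iron deficiency and phosphate starvation. With ore15-2 replicates 1 and 2 left out, the log2 fold change of KRP6 turned to 0.049, and lists not called in either setting turned direction: GH3 enzymes (adjusted p = 0.880), auxin transport (0.759), endoreplication (0.893), growth regulators (0.917) and gibberellin (0.590). Without the block genes GH3 enzymes turned (0.474). When single libraries were left out, auxin transport turned without ore15-2 replicate 2, and type-A ARRs, meristem regulators, photosynthetic tissue and ethylene without ore15-2 replicate 3. Over these settings their adjusted p ranged from 0.747 to 0.976, 0.444 to 0.904, 0.409 to 0.855, 0.0109 to 0.532 and 0.542 to 0.968. The photosynthetic list passed, as lower, without ore15-2 replicate 2, without both shallow ore15-2 libraries and without the block genes. Type-A ARRs passed, as higher, without both shallow ore15-2 libraries, and the PLATZ list passed, as lower, without ore15-2 replicate 3 (0.0218). Leaving out both shallow libraries keeps 1 ore15-2 library, so calls in that setting rest on the spread between Col libraries only. The endodermis list passed, as higher, in 5 settings, with adjusted p between 2.62e-05 and 0.0293.

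With a replicate block 1641 genes were called on the counts and 1136 on the RPKM values, 7 lists were called, and the odds ratio was 7.56. Of the 54 named genes past the threshold 48 stayed past it with the replicate block. The 6 lost were RRN18, RRN26, WES1, YUC6, CKX5 and AT2G01818. A pooled ratio has no model terms, so the block gives no value for the ORE15 level, and limma-voom and the stricter filter gave none because ORE15 was filtered out. Deviations of same-numbered libraries correlated at 0.06, 0.08 and -0.20, so no sign of pairing by number was seen, and not every library correlated best with its own number. The deviations of ore15-2 replicates 2 and 3 correlated at -0.81 with each other. A weaker effect shared by a number could be hidden under that difference, so pairing is not excluded. With 6396903 counts in the shallowest library, 3 counts are 0.596 CPM, above the Col mean of ORE15 (0.534 CPM), so a fall from that level was not detectable in that library alone.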

Other observations

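The tests on library quality for the block and the root hair genes, on an extra copy, on depth and the mitochondrial share, on RNA without a poly(A) tail, on mature tissue, on RSL4 and on other splits of the samples were chosen after the result was seen. The genes given next were also chosen after their values were seen.

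A few genes were close to absent in one genotype. AT2G01422 had 267, 269 and 311 counts in Col and 0 in each ore15-2 library, at least 32.7-fold lower against a floor of 3 counts per library, and AT2G14247, which overlaps a noncoding gene by 233 bp, had 142, 151 and 160 counts and 0, at least 17.5-fold lower. AT1G75945, at 28515245 to 28515916 on chromosome 1 (TAIR10.1) and outside the raised block, had 3, 0 and 0 counts in Col and 65, 65 and 210 in ore15-2, a ratio of 245.7 with an exact 95% counting interval of 83.4 to 1197. AT3G12900, written into the iron deficiency list as S8H but left out because the reference does not give that name, had 59, 93 and 80 counts in Col and 3, 1 and 2 in ore15-2, 17.8-fold lower with an interval of 8.07 to 49.1.

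DIN10, BT1 and SEN1, which are known to be induced when sugar is low, all fell, and the hypothesis was that the carbon starvation response is less active in these ore15-2 root tips. A list of 13 further carbon starvation genes was written before their values were seen. Of these 11 fell. ASN1, an asparagine synthetase that overlaps a neighbouring gene by 11 bp, fell by 1.89 and TPS11 fell by 1.63. All 13 had negative log2 fold changes, and the medians were -0.97, -1.30 and -0.65 in ore15-2 replicates 1, 2 and 3. The list passed camera (p = 9.06e-18, and p = 0.0171 with an estimated correlation), as the hypothesis predicted. These p-values are unadjusted because the list was tested alone, unlike the adjusted values given for the other lists. The estimated correlation between its genes was 0.36, far above the preset 0.01. By camera with an estimated correlation, the unadjusted p was 0.0151 for phosphate starvation and 0.00387 for iron deficiency. The estimates for these 2 lists were -0.03 and -0.008, below the preset. Neither of those lists passed once adjusted over all lists tested. A difference in growth or harvest between the genotypes could give the same pattern and was not tested.

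The raised block on chromosome 1 ended beside ORE15. The quality of ore15-2 replicates 1 and 2 does not account for it, since its median log2 change was 0.94 in replicate 3. GC content, exon length and expression level do not account for it either, since the block median exceeded that of genes elsewhere in the same classes by 0.94. An extra copy of the segment in ore15-2 is a candidate explanation: the median fold was between 1.84 and 1.93 in the 3 libraries, and the median log2 fold changes of the least and most expressed block genes (the outer terciles) were 0.88 and 1.07, 0.18 apart, close to the limit of 0.2 used for it. DNA copy number was not measured, so this remains a hypothesis.

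Libraries ore15-2 replicate 1 and 2 stood apart from the rest. Lower depth does not account for their mitochondrial share, since depth leaves an expected share as it is and the exact 95% counting interval of the lower of the 2 shares began at 2.89%, against at most 0.328% in the other libraries. For nuclear genes the limit of 0.3 set for depth did not decide. Thinned to 6396903 counts in 20 draws, ore15-2 replicate 3 had an interquartile range of log2 changes of 0.298 (0.2942 to 0.3002), on both sides of that limit. Col replicates 1, 2 and 3 thinned the same way had 0.155, 0.129 and 0.140. All of these lay below the 0.419 and 0.718 of ore15-2 replicates 1 and 2, which argues against depth alone as the cause of the spread in these 2 libraries. More RNA without a poly(A) tail in these libraries may contribute. The lowest median log2 change of mitochondrial, chloroplast and ENSRNA genes in them was 2.12, against at most 0.34 in replicate 3. These values cannot decide it, because the mitochondrial rise is part of what is to be explained and tails were not measured. RNA breakdown by transcript length cannot be told apart from other causes, the Spearman correlation of change with exon length across genes, which are not independent replicates, being -0.15 and -0.24.

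Root hair genes were higher in ore15-2. More mature tissue in the samples was predicted to raise the phloem, xylem and endodermis lists together, and they did not rise together. The phloem median was -0.35 and the xylem median -0.20, while the endodermis median was 0.25, with 12 of 13 genes positive. The xylem call was also lost in several settings. These lists moved in different directions, so a change in the mix of tissues cannot be excluded. The quality of ore15-2 replicates 1 and 2 does not account for the rise, since the root hair median in replicate 3 was 0.84 and 21 of 22 genes were positive there. RSL4, at 1.08, rose with the block, while its upstream regulators RHD6 and RSL1 were at 0.04 and 0.25. Whether RSL4 raised the list or disruption of ORE15 did cannot be told apart, since each ore15-2 library carries both the insertion and the raised block.

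The 6 libraries split 3 against 3 in 10 ways, so no share under 0.05 is possible. Only 1 split, the real one, gave as many changed genes (1854, the highest other being 0), and the same held on the RPKM values (1110 and 0). For gene lists 3 splits gave as many as the 6 of the real one, the highest other being 7.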
